A study of Rattus norvegicus with 10 samples.

How the data were processed

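RNA sequencing libraries of EDTA-released distal colon epithelial cells from 5 control rats and 5 rats fed chow with 1% w/w sodium cholate were compared. Per the series design text, the 5 rats per diet with the highest RNA concentration were sequenced, a selection that was not random. Stranded poly(A) libraries were sequenced on an Illumina HiSeq instrument, and reads were demultiplexed with bcl2fastq 1.8.4 and aligned to rn6 with BWA-MEM 0.7.12-r1039, which is not a splice-aware aligner. The counting program and its strand setting are not given in the sources used here, so counts of genes that overlap antisense genes or have close paralogs are uncertain. The deposited table holds raw counts per gene, and beside them the authors' normalized signal, which is CPM on the TMM effective library size from edgeR 3.16.2. The other deposited columns are gene lengths and annotation coordinates, in bases. The authors' criteria were a false discovery rate under 1% and a fold change over 2.

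The raw counts were used for every comparison. The normalized signal was used only to read the authors' scaling factors. Of 23422 genes in the table, 6442 had no reads. Total counts were 25874196, 25004778, 25957175, 35927355 and 19883925 in control rats 1, 2, 5, 6 and 9, and 25780869, 45285762, 37391258, 18584910 and 14337356 in cholate rats 3, 4, 7, 8 and 11. A count of 0 allows up to 3 counts in a library, which is 0.0662 CPM in the deepest and 0.209 CPM in the shallowest. Intervals and this floor cover counting error only.

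Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Genes were filtered with filterByExpr by diet, scaled by TMM and tested with the edgeR quasi-likelihood F test with robust estimation, with diet as the only term, and p values were adjusted by Benjamini-Hochberg over the 12385 genes tested. A gene was called at an adjusted p under 0.01 and an absolute log2 fold change over 1. Standard errors were taken as the absolute log2 fold change over the square root of F, which is approximate. The common biological coefficient of variation was 34.3%. The method was tested on simulated data, in which it found 76 of 100 genes changed by 1.5 on the log2 scale and 90 of 100 changed by 2.5 with 3 false calls, and called 2 of 2 changed and 0 of 30 unchanged sets. The changed genes were taken only from those with a mean of at least 5 CPM, so finding changes below that level was not tested. All simulated genes were drawn independently of each other. The set result therefore does not show how often correlated sets would be called falsely. Nor do the 3 false calls cover variation that genes share across rats. No paired analysis was possible because no rat number is shared between the diets.

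The test, thresholds, gene lists and naming rule were fixed before the data were examined. The rule named the 12 called-higher and 12 called-lower genes with the largest change among those with a symbol, a mean of at least 5 CPM in either diet and no overlap between diets, and the 5 per direction with the smallest adjusted p. It also named up to 4 called members of each list, or the member with the smallest adjusted p where none was called, and the measured members of the bile acid list with at least 1 CPM. It took 105 genes, all of which entered the alternative settings, and the text names some of them. Results for some genes taken by the rule are not reported here. A further 9 genes (Trpv6, S100g, Slc37a2, Tnni1, Myh11 and Padi1 to Padi4) were chosen after their values were seen.

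The 38 lists, 25 of pathways and 13 of cell types, were tested by camera with a preset inter-gene correlation of 0.01 and called at an adjusted p under 0.05. Camera with an estimated correlation and fry, which tests whether the genes of a set move on balance 1 way without reference to other genes, were run beside it. The pathway lists were bile acid receptors and transport, absorptive ion and water transport, secretory ion transport and its regulators, xenobiotic metabolism, NRF2 antioxidant response, endoplasmic reticulum stress, proliferation, intestinal stem cell and Wnt target, apoptosis and p53 response, inflammatory cytokines and mediators, interferon response, MHC class II presentation, antimicrobial and mucosal defence, tight junction, cholesterol synthesis and uptake, fatty acid synthesis, PPAR targets and fatty acid oxidation, epidermal growth factor ligands and epithelial repair, immediate early genes, glucocorticoid and aldosterone response, circadian clock, hypoxia and glycolysis, mitochondrial respiratory chain, polyamine, amino acid and nutrient transport, and small intestinal enterocyte. The cell type lists were differentiated colonocyte, goblet, enteroendocrine, tuft, T and NK, B and plasma, macrophage and dendritic, and granulocyte and mast cells, fibroblast and stroma, smooth muscle, endothelium and blood, enteric neuron and glia, and colon segment identity. Of 1025 members 1020 were found by symbol or Entrez identifier and 771 were measured, and Sis, Lyz1, Cyp11b1, Ighm and Prac1 were not matched. Cell type means and 6 library properties were compared by exact 2-sided permutation over all assignments, for which the smallest possible p is 0.00794, with Benjamini-Hochberg adjustment within each family.

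The alternatives set beforehand were other scalings, filters, tests, thresholds, 1 surrogate variable, and leaving out each rat. After seeing the data, sets of 6 and of 4 rats defined from the first principal component, the surrogate variable for the lists, and 10000 random lists matched on expression and exon length were added. The labels give no batch. GC content was not analysed here.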

Results

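RNA was sequenced from epithelial cells of the distal colon of male Wistar Munich rats. Of 12 rats, 6 were switched after 3 days of acclimatization to chow with 1% w/w sodium cholate, the sodium salt of the primary bile acid cholic acid, and the diets lasted 10 days. The cells were released from the colon with EDTA, which loosens the epithelial sheet. Libraries were made from the 5 rats per diet with the highest RNA concentration, so the groups were control rats 1, 2, 5, 6 and 9 and cholate rats 3, 4, 7, 8 and 11. Total counts per library ran from 14337356 in cholate rat 11 to 45285762 in cholate rat 4. Levels are CPM after TMM scaling, as mean ± SD over 5 rats per diet. Changes are log2 fold changes of cholate over control, with an approximate standard error (SE), and adjusted p values for single genes are from the edgeR quasi-likelihood test.

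The comparison asked how 10 days of dietary cholate changed gene expression in distal colon epithelium. Slc51b, the beta subunit of the basolateral bile acid exporter, rose from 10.3 ± 2.60 to 77.1 ± 37.2 CPM. Arg2, the mitochondrial arginase, rose from 14.7 ± 4.53 to 143.3 ± 44.9 CPM, and 7 of 28 measured genes of cholesterol synthesis and uptake rose. Slc39a2, a zinc transporter, fell from 9.25 ± 2.38 to 0.142 ± 0.0628 CPM, and Dio1, a deiodinase of thyroid hormone, fell from 92.6 ± 24.6 to 7.54 ± 2.39 CPM. Of 31 measured interferon response genes, 4 fell and none rose.

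Of 12385 genes tested, 398 had an adjusted p under 0.01 and a fold change over 2, 136 of them higher and 262 lower on cholate. The fold change exceeded 4 in 174 called genes, 54 higher and 120 lower. In 397 of the 398 the 5 cholate values lay wholly above or wholly below the 5 control values. This separation held for 13.1% of all genes tested, against 0.794% by chance. The number called was 168 without control rat 2, 192 without control rat 1, 200 without control rat 6, 207 without cholate rat 4 and 221 without cholate rat 7. Of the 83 called genes taken by the naming rule, 40 were called whichever rat was left out, and the other 43 lost the call in at least 1 of these 10 fits, with no change of direction. The test of glmTreat against a fold of 2 kept 20 of the 83, and 15 lost the call in at least 1 other setting that used all 10 rats.

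**Figure D1:**
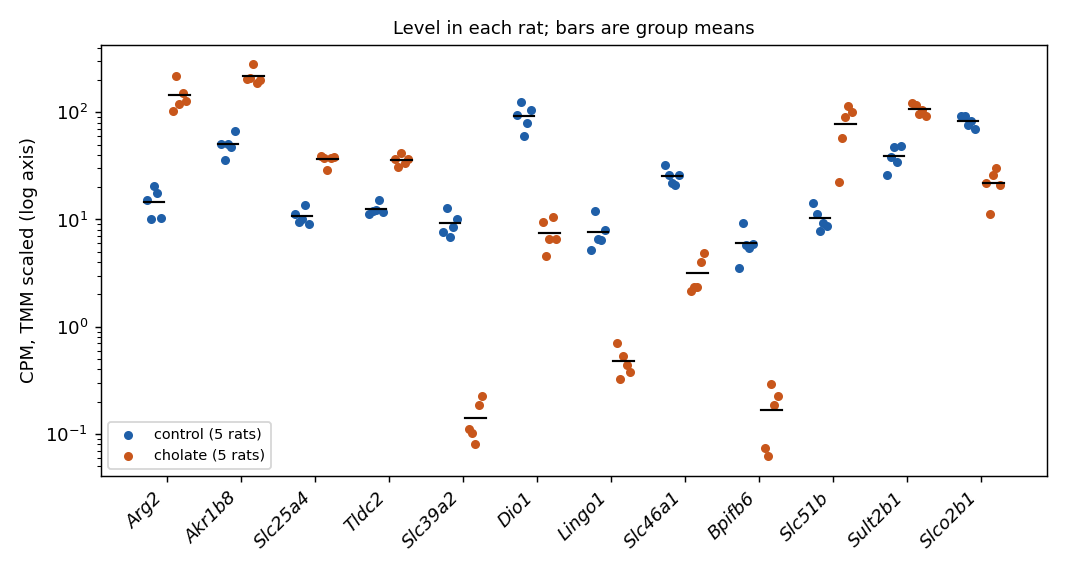
Levels of 12 genes in each rat, in TMM-scaled CPM on a log axis, with control rats in blue, cholate rats in orange and a bar at each group mean. From the left, the genes are 4 called higher and 5 called lower with small adjusted p, then the 3 called members of the bile acid list, and in each the 5 cholate values lie wholly on one side of the 5 control values.

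Of 16 measured genes of bile acid receptors and transport, 2 rose and 1 fell, and adjusted over the list alone 3 rose and 1 fell. Slc51b (Entrez 300790, rn6 chromosome 8, 70930196 to 70938559, minus strand) rose by 2.91 (SE 0.40, adjusted p = 0.00172). This call was lost by glmTreat and among controls 1, 2 and 6 and cholate rats 3, 4 and 7 alone (2.32, adjusted p = 0.0199). Sult2b1, a sulfotransferase of hydroxysteroids (Entrez 292915, chromosome 1, 101712254 to 101774683, minus strand), rose from 38.7 ± 9.27 to 106.4 ± 12.8 CPM, a log2 change of 1.46 (SE 0.18, adjusted p = 0.00108). Sult2b1 overlaps the antisense gene Lmtk3, and whether counting used the strand is not given in the sources used here. Slco2b1, an uptake transporter of organic anions (Entrez 140860, chromosome 1, 164623313 to 164671612, minus strand), fell from 82.7 ± 9.46 to 21.9 ± 7.01 CPM, a log2 change of -1.92 (SE 0.23, adjusted p = 0.00106). Slc51a, the alpha subunit of the exporter, had a log2 change of 2.13 (adjusted p = 0.0438, but 2.95 without control rat 1 and 1.25 among those 6 rats), and Fabp6, the ileal bile acid binding protein, one of 2.84 (adjusted p = 0.0237) at 1.46 ± 0.830 CPM on cholate. Neither was called, though both were by DESeq2 and the edgeR exact test. Slc51a was called in 3 settings in all, its log2 change running from 1.25 to 3.79 over the settings. Fabp6 was called also by limma-voom with quality weights, with 1 surrogate variable and among the 6 rats. The bile acid receptor Nr1h4 had a log2 change of -0.24 (adjusted p = 0.413), its target Nr0b2 0.53 (adjusted p = 0.261), the vitamin D receptor Vdr -0.99 (adjusted p = 0.0514), Nr1i2 -0.16 (adjusted p = 0.749) and Nr1i3 -0.53 (adjusted p = 0.577, but -1.14 without cholate rat 8). The others were not called either, with log2 changes of 0.56 for Abcc4, 0.43 for Slco3a1, 0.19 for Abcc3, 0.15 for Slco4a1, -0.26 for S1pr2 and -0.64 for Chrm3. The list did not pass camera (adjusted p = 0.28).

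Of 28 measured genes of cholesterol synthesis and uptake, 7 rose and none fell, and adjusted over the list alone 9 rose. The median log2 change was 0.86, and camera called the list (adjusted p = 4.52e-15, but adjusted p = 0.0507 with an estimated correlation). Insig1, which retains the sterol sensor in the endoplasmic reticulum, rose by 1.56 (SE 0.24, adjusted p = 0.00285), the sterol oxidase Msmo1 by 1.42 (SE 0.19, adjusted p = 0.0015) and Acat2, which overlaps the antisense gene LOC102553528, by 1.33 (SE 0.18, adjusted p = 0.0016). In fatty acid synthesis 2 of 19 measured genes rose, the desaturase Scd by 3.21 (adjusted p = 0.00333, call lost without control rat 1, 2 or 6) and the acyltransferase Dgat2 by 1.67 (adjusted p = 0.00142). Adjusted over the list alone 3 rose and 2 fell, and camera called the list higher (median 0.57, adjusted p = 0.00167, but adjusted p = 0.112 with an estimated correlation). Of 30 measured PPAR targets and genes of fatty acid oxidation, 1 rose and 1 fell, the same numbers as when adjusted over the list alone. The fatty acid binding protein Fabp2 rose by 2.34 (adjusted p = 0.00291, call lost without control rat 2), and the list did not pass camera (adjusted p = 0.462).

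**Figure D2:**
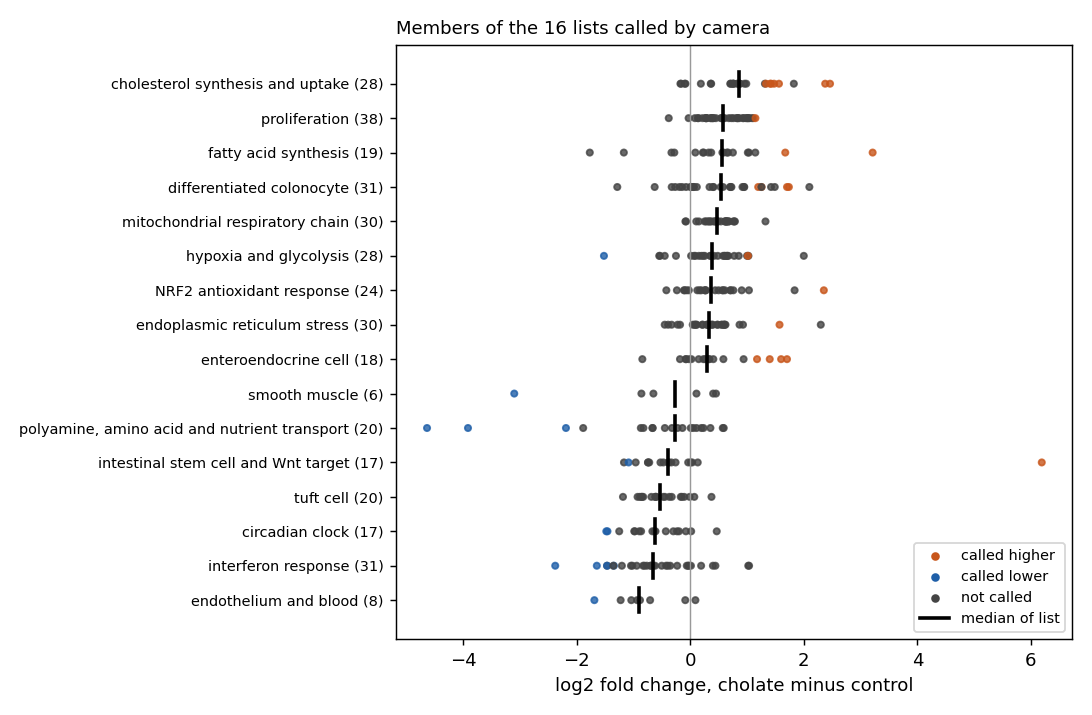
Log2 fold changes of the measured members (number in parentheses) of the 16 lists called by camera with a preset inter-gene correlation of 0.01, with called members in colour and a black bar at each median. The medians run from -0.91 for endothelium and blood to 0.86 for cholesterol synthesis and uptake, and with an estimated correlation 0 lists were called by camera, 9 having an unadjusted p under 0.05, while fry called 17.

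Among called genes with a symbol, a mean of at least 5 CPM in either diet and no overlap between diets, the largest increase was that of the fatty acid binding protein Fabp4, by 5.28, from 0.305 ± 0.199 to 11.4 ± 7.92 CPM. The next were Slurp1 (5.15), Fer1l4 (4.84), the goblet cell peptide Spink4 (4.76), Cyp4f1 (4.18), C2cd4a (3.78), Fabp5 (3.53), the secreted phospholipase Pla2g2a (3.42), the fatty acid hydroxylase Fa2h (3.37), Arg2 (3.29), Sptssb (3.22), a subunit of serine palmitoyltransferase, and Scd. Spink4 rose from 3.37 ± 3.63 to 90.0 ± 47.6 CPM and Pla2g2a from 59.2 ± 60.2 to 634.8 ± 239.7 CPM. Arg2 (Entrez 29215, chromosome 6, 102311097 to 102338406, plus strand) rose by 3.29 (SE 0.28, adjusted p = 0.00031). Small adjusted p values among increases were also those of the aldo-keto reductase Akr1b8 (log2 change 2.10, adjusted p = 0.000321), the ADP/ATP carrier Slc25a4 (1.75, adjusted p = 0.00035) and Tldc2 (1.52, adjusted p = 0.000417). Of the 10 fits that left out 1 rat, the call was lost in 6 for Cyp4f1, 5 for Sptssb, 4 each for Spink4 and Pla2g2a, and 2 for Fer1l4. The log2 change was 5.80 for Slurp1 without control rat 5, 5.55 for Spink4 without control rat 9, 4.29 for Pla2g2a without control rat 6 and 3.32 for Cyp4f1 without cholate rat 8. Cyp4f1 and Akr1b8 have close paralogs, and how reads shared between genes were counted is not given in the sources used here.

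By the same rule the largest decreases were those of the neighbouring paralogs Retnla (-9.03, SE 1.58) and, further down, Retnlb (-5.61, SE 1.07), which encode secreted resistin-like proteins. Their control levels varied widely, 62.1 ± 102.8 and 38.7 ± 58.5 CPM. Between them came Dnase1 (-7.20), Actn2 (-7.07), an actin cross-linker of striated muscle, Akap2 (-6.19), which lies next to Palm2, and Slc39a2 (-6.14), and then Bpifb6 (-5.18), Aldh1a1 (-4.72), the aminopeptidase Enpep (-4.50), Shc2 (-4.40), Speg (-4.35) and Sgce (-4.19). The log2 change of Retnla was -7.07 without control rat 9 and -11.13 without cholate rat 11. Its call was lost in 6 of the 10 fits that left out 1 rat. The log2 change of Retnlb was -4.01 without control rat 9, with the call lost in 8 fits. Dnase1 had -5.82 without control rat 1 and -7.94 without cholate rat 11, with the call lost in 5, and Enpep -3.88 without control rat 1, with the call lost in 3. The changes of Actn2 without cholate rat 7 (-7.72), Akap2 without cholate rat 4 (-7.36) and Speg without cholate rat 11 (-4.98) stayed called. Limma-voom did not call Retnla, Retnlb or Dnase1, nor limma-trend Dnase1. Aldh1a1, an enzyme of retinoic acid synthesis, fell from 257.5 ± 117.2 to 9.78 ± 5.44 CPM. Slc39a2 (Entrez 305846, chromosome 15, 28295044 to 28297688, plus strand) had the smallest adjusted p of all genes (SE 0.34, adjusted p = 1.84e-05). Dio1 (Entrez 25430, chromosome 5, 126894837 to 126911532, minus strand) fell by 3.62 (SE 0.28, adjusted p = 0.000309). Lingo1 (log2 change -3.98, adjusted p = 0.00031) and the folate transporter Slc46a1 (-3.03, adjusted p = 0.00035) also fell.

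Of 20 measured genes of polyamine, amino acid and nutrient transport, 3 fell and none rose, the same numbers as when adjusted over the list alone. These were the thiamine transporter Slc19a3 (-4.64, adjusted p = 0.00399), with 110 counts in controls and 4 on cholate, the manganese exporter Slc30a10 (-3.92, adjusted p = 0.00571) and the peptide transporter Slc15a1 (-2.19, adjusted p = 0.00865). Slc30a10 and Slc15a1 overlap antisense genes. Leaving out 1 rat ended the call in 5 of 10 fits for Slc19a3, 6 for Slc30a10 and 8 for Slc15a1, with log2 changes of -7.42 for Slc19a3 without cholate rat 7 and -4.71 for Slc30a10 without cholate rat 4. Slc15a1 was also lost with a mean of at least 5 CPM required, and Slc19a3 by limma-trend. Camera called the list lower (median -0.27, adjusted p = 0.00677, but adjusted p = 0.133 with an estimated correlation). The list was not called among controls 1, 2 and 6 and cholate rats 3, 4 and 7 (adjusted p = 0.0768), nor beyond random lists matched on exon length and expression (adjusted share 0.0655). Of 29 measured genes of xenobiotic metabolism, 3 rose and 2 fell, and adjusted over the list alone 3 rose and 3 fell. Akr1b8 and LOC100361492, named Cyp2c55 in a newer gene table, were among the increases (2.10 and 2.19), and Aldh1a1 and Cyp2j4 were the decreases (-4.72 and -2.75). The list did not pass camera (adjusted p = 0.298). None of 27 measured genes of absorptive ion and water transport was called, nor was any when adjusted over the list alone, and the water channel Aqp3 came nearest (1.32, adjusted p = 0.021). Aqp3 was called without cholate rat 11 (1.51), among controls 1, 2 and 6 and cholate rats 3, 4 and 7, by DESeq2, by the edgeR exact test and by limma-voom with quality weights. None of 23 measured genes of secretory ion transport and its regulators was called, and 1 fell when adjusted over the list alone. The potassium channel Kcnq1 had the smallest adjusted p (0.0138) but a log2 change of only -0.53, under the fold limit. The 1 gene that fell was therefore another. Neither list passed camera (adjusted p = 0.749 and 0.425).

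Of 38 measured proliferation genes 2 rose, thymidine kinase Tk1 from 43.1 ± 5.95 to 95.4 ± 20.9 CPM (adjusted p = 0.00268) and cyclin Ccnb1 by 1.11 (adjusted p = 0.00332), and none fell. Adjusted over the list alone 6 rose, and camera called the list higher (median 0.57, adjusted p = 4.98e-10, but adjusted p = 0.229 with an estimated correlation). Of 30 measured genes of the mitochondrial respiratory chain none was called and 1 rose when adjusted over the list alone, and camera called the list higher (median 0.48, adjusted p = 4.47e-08, but adjusted p = 0.336 with an estimated correlation). These genes are short, with a median exon length of 1215 against 2921.5 bases for all genes tested. Random lists matched on exon length and expression had a median log2 change of 0.28, so the list stood less far from those (adjusted share 0.0104). Uqcrc2, of complex III, had the smallest adjusted p of that list (0.00858) at a log2 change of 0.46. Of 24 measured genes of the NRF2 antioxidant response, heme oxygenase Hmox1 rose by 2.35 (adjusted p = 0.00852) and 2 rose when adjusted over the list alone (camera higher, median 0.36, adjusted p = 0.0029, but adjusted p = 0.19 with an estimated correlation). The matched random lists of the NRF2 genes had a median of 0.18, and the list did not pass beyond them (adjusted share 0.0623). Of 30 measured genes of endoplasmic reticulum stress, Trib3 rose by 1.57 (adjusted p = 0.00333), also the 1 gene adjusted over the list alone (camera higher, median 0.33, adjusted p = 0.00659, but adjusted p = 0.369 with an estimated correlation). Of 28 measured genes of hypoxia and glycolysis, the glycolytic enzyme Pgk1 rose by 1.02 and the hypoxia-inducible factor Epas1 fell by 1.52, also 1 and 1 adjusted over the list alone (camera higher, median 0.39, adjusted p = 0.00544, but adjusted p = 0.133 with an estimated correlation). None of 23 measured genes of apoptosis and the p53 response was called, nor was any when adjusted over the list alone. Gadd45a had the smallest adjusted p (0.0128) at a log2 change of 0.66, and the list did not pass camera (adjusted p = 0.9). The Hmox1 call was lost in 8 of the 10 fits that left out 1 rat and with a mean of at least 5 CPM required. It was also lost by limma-voom with or without quality weights, by limma-trend and among controls 1, 2 and 6 and cholate rats 3, 4 and 7. Other calls lost on leaving out 1 rat were Epas1 in 9 of 10 fits, Ccnb1 in 5, Pgk1 in 4, Trib3 in 3 and Tk1 in 2. Scaling by library size alone ended the calls of Epas1 and Pgk1. That of Pgk1 was also lost under upper quartile scaling and with a mean of at least 5 CPM required.

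Of 31 measured markers of differentiated colonocytes 4 rose and none fell, and adjusted over the list alone 6 rose and 1 fell. The carbonic anhydrase Car1 (Entrez 310218, chromosome 2, 88185204 to 88227486, plus strand) rose from 866.4 ± 136.0 to 2823 ± 846.0 CPM (1.70, SE 0.23, adjusted p = 0.0015), Car4 from 206.8 ± 41.3 to 473.8 ± 46.1 CPM, Krt20, which overlaps an antisense gene, by 1.26 and Prap1 by 1.74. Camera called this list higher (median 0.53, adjusted p = 1.09e-05, but adjusted p = 0.101 with an estimated correlation). Of 18 measured enteroendocrine markers 4 rose and none fell, with equal numbers when adjusted over the list alone: proglucagon Gcg from 67.2 ± 11.6 to 177.4 ± 36.1 CPM (1.40, adjusted p = 0.00129), Pyy by 1.60, Cck by 1.18 and Neurog3 by 1.70 (camera higher, median 0.29, adjusted p = 0.00355, but adjusted p = 0.366 with an estimated correlation). The enteroendocrine list was not called among controls 1, 2 and 6 and cholate rats 3, 4 and 7 (adjusted p = 0.0796), nor beyond matched random lists (adjusted share 0.0616). Of 17 measured stem cell and Wnt target genes, Olfm4 rose and the ubiquitin ligase Rnf43 fell by 1.09 (adjusted p = 0.00251), also 1 and 1 adjusted over the list alone. Olfm4 had 3 counts over the control rats and 312 over the cholate rats, a ratio of 99.7 (95% exact interval 33.8 to 486). That interval covers counting error only and not the spread between rats. With rats as replicates the log2 change of Olfm4 was 6.19 (SE 0.83, adjusted p = 0.00164), at 1.91 ± 1.58 CPM on cholate. Camera called this list lower (median -0.39, adjusted p = 0.0186, but adjusted p = 0.369 with an estimated correlation). Of 20 measured tuft cell markers none was called, nor was any when adjusted over the list alone, Gnat3 coming nearest (-1.19, adjusted p = 0.0131, but called in 5 other settings, DESeq2 among them), and camera called the list lower (median -0.54, adjusted p = 0.0118, but adjusted p = 0.574 with an estimated correlation). Of 21 measured goblet cell markers Spink4 rose and Retnlb fell, 1 and 2 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.425). Fits that left out 1 rat lost the call of Neurog3 8 times of 10, of Prap1 7, of Cck 4, of Krt20 3 and of Pyy 1, and those of Car1, Car4, Gcg, Olfm4 and Rnf43 in none. Limma-trend did not call Neurog3, Prap1 or Olfm4, and Neurog3 was also lost by limma-voom and with no filter beyond 1 count.

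Of 31 measured interferon response genes 4 fell, Zbp1 (-2.38), the proteasome subunit Psmb8 (-1.65), Oas1a (-1.47) and Ifi44 (-1.35), and 5 fell when adjusted over the list alone. Camera called the list lower (median -0.66, adjusted p = 0.000131, but adjusted p = 0.112 with an estimated correlation). The mean of the T and NK cell markers was lower too (-0.69, adjusted p = 0.0413 by an exact permutation test), and whether the interferon genes follow it was not tested. Of 18 measured inflammatory cytokines and mediators the chemokines Ccl28 (-1.19) and Cx3cl1 (-1.01) fell, and adjusted over the list alone 1 rose and 2 fell (camera, adjusted p = 0.425). Of 20 measured genes of antimicrobial and mucosal defence, Pla2g2a rose, and Retnlb and the lipopolysaccharide binding protein Lbp (-2.18, adjusted p = 0.0045) fell, 1 and 3 adjusted over the list alone (camera, adjusted p = 0.7). None of 10 measured genes of MHC class II presentation was called, nor was any when adjusted over the list alone, Ctss having the smallest adjusted p at -0.61 (camera, adjusted p = 0.222). Of 17 measured circadian clock genes Cry2 (-1.46) and Nfil3 (-1.48) fell, and 3 fell when adjusted over the list alone. Camera called the clock list lower (median -0.63, adjusted p = 0.000378, but adjusted p = 0.112 with an estimated correlation). Of 20 measured genes of the glucocorticoid and aldosterone response Fkbp5 rose by 2.18 and Tsc22d3 fell by 1.14, and of 27 measured immediate early genes Csrnp1 rose by 1.06 and Jun fell by 1.58. Both lists had 1 and 1 adjusted over the list alone, and neither passed camera (adjusted p = 0.218 and 0.465). The glucocorticoid and aldosterone list (median -0.47) was called lower without cholate rat 11 (median -0.72, adjusted p = 0.0443), among controls 1, 2 and 6 and cholate rats 3, 4 and 7 (adjusted p = 0.00392) and by fry (adjusted p = 0.0471). It also lay beyond matched random lists (adjusted share 0.00338). The Csrnp1 call was lost in 9 of the 10 fits that left out 1 rat and under upper quartile and library size scaling, the other 3 filters, limma-voom with or without quality weights and limma-trend. That of Cx3cl1 was also lost under median-of-ratios scaling, with no filter beyond 1 count, by DESeq2, by limma-voom with or without weights and by limma-trend. Cx3cl1 and Cry2 lost theirs in 9 such fits each, Oas1a, Nfil3, Jun, Tsc22d3 and Lbp in 5 each, Psmb8 in 4 and Fkbp5 in 2, while Zbp1, Ifi44 and Ccl28 kept theirs.

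Of 28 measured genes of epidermal growth factor ligands and epithelial repair the cornified envelope gene Sprr1a rose by 5.40 (adjusted p = 0.00226, 6.69 without control rat 5, call lost without control rat 2), also the 1 gene adjusted over the list alone, with 7 counts in controls and 313 on cholate, and the list did not pass camera (adjusted p = 0.7). None of 22 measured tight junction genes was called, nor was any when adjusted over the list alone, F11r having the smallest adjusted p at -0.35 (camera, adjusted p = 0.664). Of 17 measured markers of small intestinal enterocytes Fabp2 rose and Slc15a1 fell, and adjusted over the list alone 4 rose and 2 fell (camera, adjusted p = 0.648, but median -0.63 and beyond matched random lists at an adjusted share of 0.00095). Of 13 measured genes of colon segment identity LOC100361492 rose and Hoxd12 fell by 1.98, also 1 and 1 adjusted over the list alone (camera, adjusted p = 0.425). The median and mean differed in sign for absorptive ion and water transport (-0.03 and 0.06, test direction up), apoptosis and the p53 response (0.10 and -0.03, up), tight junction (0.01 and -0.05, down) and granulocytes and mast cells (0.08 and -0.08, down).

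Of 76 measured markers in the 8 lists of immune, stromal, muscle, endothelial and neural cells, 5 fell and 2 rose. None of these lists was called with an estimated correlation. Of 6 measured smooth muscle markers desmin (Des, Entrez 64362) fell from 38.2 ± 8.05 to 4.50 ± 1.68 CPM (-3.10, SE 0.29, adjusted p = 0.000417), of 8 of endothelium and blood Vwf fell by 1.69, of 16 of T and NK cells Cd7 (-1.93) and Il2rb (-2.04) fell, and of 5 of enteric neurons and glia Ret fell by 1.88, each also when adjusted over the list alone. Flt3 rose by 2.83 among 20 macrophage and dendritic cell markers, also adjusted over the list alone. Dpep1 rose by 2.70 among 7 of fibroblasts and stroma, where 1 rose and 1 fell adjusted over the list alone. None of 5 markers of B and plasma cells (nearest Prdm1, 2.48, adjusted p = 0.0377) or of 9 of granulocytes and mast cells (nearest Prg2, -1.97, adjusted p = 0.0261) was called, nor was any when adjusted over the list alone. Prg2 was called without control rat 6 (-2.22), by DESeq2, by the edgeR exact test and with 1 surrogate variable, and Prdm1 in 5 settings, DESeq2 among them. Camera called smooth muscle (median -0.27, adjusted p = 0.0435, but adjusted p = 0.19 with an estimated correlation) and endothelium and blood lower (median -0.91, adjusted p = 0.0367, but adjusted p = 0.19 with an estimated correlation). The smooth muscle call was lost without any rat except cholate rat 4, at an adjusted p of up to 0.329, and the endothelial one without control rat 6 or 9 or cholate rat 3 or 7, at up to 0.0809. The smooth muscle median turned positive, at 0.02 to 0.14, without control rat 1, 2, 6 or 9 or cholate rat 8 or 11. With 1 CPM required in 5 samples it was 0.10, and the camera call was lost (adjusted p = 0.0506). Single-gene calls lost on leaving out 1 rat were Cd7 and Flt3 in 9 of 10 fits each, Ret in 6, and Vwf, Il2rb and Dpep1 in 5 each, with Des kept. The Cd7 call was also lost under median-of-ratios scaling, the other 3 filters and limma-voom, and that of Il2rb by limma-trend. Camera did not call T and NK cells (adjusted p = 0.0719), neurons and glia (0.247), macrophages and dendritic cells (0.392), B and plasma cells (0.425), fibroblasts and stroma (0.656) or granulocytes and mast cells (0.663). T and NK cells were called lower without control rat 1 (median -0.86, adjusted p = 0.0363), cholate rat 3 (-0.61, 0.0422) or cholate rat 4 (-1.04, 0.0156), and neurons and glia by fry (adjusted p = 0.0245).

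The mean log2 CPM of each of the 13 cell type lists was compared by an exact 2-sided permutation test over all assignments of rats to diets. The colonocyte mean rose from 8.18 ± 0.105 to 8.67 ± 0.121, while those of smooth muscle (-0.62) and endothelium and blood (-0.81) were lower, each with an adjusted p of 0.0344 and no overlap between diets (exact p = 0.00794, the smallest possible). The T and NK cell mean (-0.69) and that of neurons and glia (-0.60) also passed (adjusted p = 0.0413 for both). The enteroendocrine (0.39, adjusted p = 0.0516) and tuft cell differences (-0.50, adjusted p = 0.0884) did not pass, nor did the other 6. Among those 6, colon segment identity (-0.21) turned higher on cholate and passed by the median of the markers (adjusted p = 0.0258). Most of the smooth muscle difference came from Des (-3.10), the other 5 markers having log2 changes of -0.86 for Myh11, -0.65 for Myl9, 0.11 for Smtn, 0.40 for Mylk and 0.45 for Tpm2. It lay between -0.01 and -0.21 in the 6 fits without 1 rat that measured 7 markers (controls 1, 2, 6 and 9, cholate rats 8 and 11). The marker added there was Synm, at 5.01 to 8.38 CPM in cholate rats 3, 4 and 7 and at most 0.597 CPM in the other 7 rats. By the median of the markers the difference of neurons and glia turned to 0.15 (adjusted p = 0.619), and it did not pass by library size alone (adjusted p = 0.0516). T and NK cells did not pass by that median (adjusted p = 0.162), nor with markers of at least 1 CPM (-0.16, adjusted p = 0.402). With any 1 rat left out none of the 13 passed, the smallest adjusted p lying between 0.0516 and 0.103, and between 3 and 7 had an unadjusted p under 0.05. The smallest possible p was 0.00794 there too, so 1 list at that p could not pass by itself.

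Libraries also differed within each diet. The first principal component of log2 CPM took 46.8% of the variance and placed control rat 9 (57.0) and cholate rats 8 (79.6) and 11 (66.8) apart from controls 1, 2 and 6 (-46.4 to -37.8) and cholate rats 3, 4 and 7 (-31.6 to -26.7), with control rat 5 at 8.08, and did not pass the test between the diets (exact permutation p = 0.46). The second took 30.6%, with controls from -44.9 to -27.9 and cholate rats from 15.4 to 54.9. Among controls 1, 2 and 6 and cholate rats 3, 4 and 7 alone, a set chosen after the data were examined, 1003 genes were called, 310 higher and 693 lower, including 366 of the 398. Of the 83 called genes taken by the naming rule 10 lost the call there, among them Slc51b, Pla2g2a, Fabp2, Flt3, Hmox1, Csrnp1, Cx3cl1, Cyp2j4 and Dnase1. Across genes, which are not independent replicates, log2 fold changes had a Spearman correlation of -0.27 with annotated exon length, and called genes were 45 higher and 38 lower in the shortest of 5 length classes against 9 and 60 in the longest. No property of the libraries passed the test between diets with all 10 rats, with ribosomal protein genes at 1.00 ± 0.0896 and 1.18 ± 0.174% of counts (exact permutation p = 0.0794, adjusted p = 0.476) and mitochondrially encoded genes at 18.8 ± 3.07 and 15.9 ± 3.10% (exact permutation p = 0.206, adjusted p = 0.524). Without cholate rat 7, 1 property had an unadjusted p under 0.05.

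**Figure D3:**
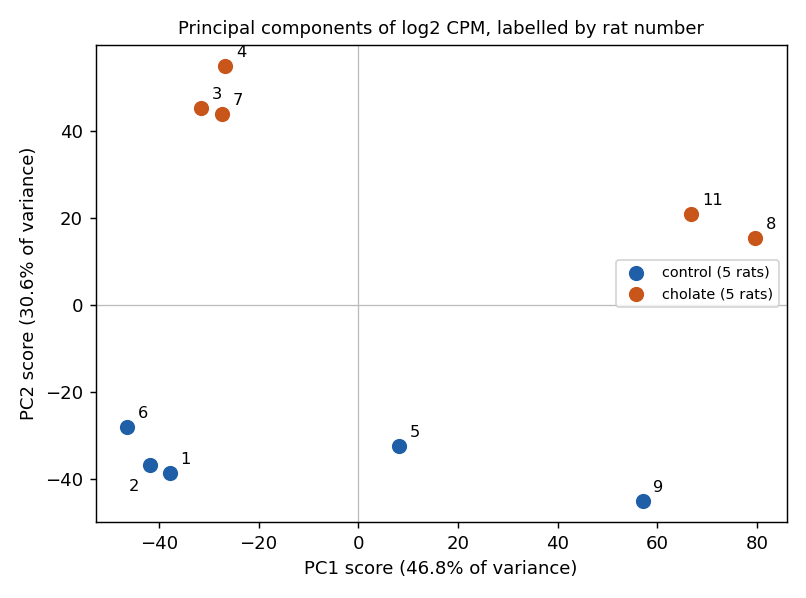
Scores of the 10 libraries on the first 2 principal components of log2 CPM, labelled by rat number, with control rats in blue and cholate rats in orange. The first component takes 46.8% of the variance and the diets lie apart on the second, which takes 30.6%.

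**Figure D4:**
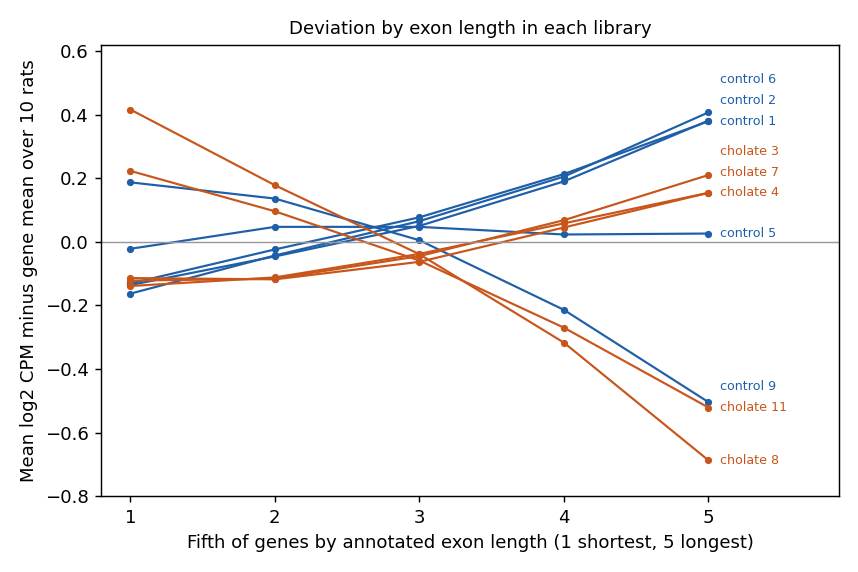
Mean log2 CPM of each library minus the gene's mean over the 10 rats, for 5 classes of genes by annotated exon length, with control rats in blue and cholate rats in orange. The longest minus the shortest class averaged 0.191 in controls and -0.191 on cholate, an exact permutation p of 0.286 for the difference, and control rat 9 and cholate rats 8 and 11 run downward. This difference was 0.51, 0.517 and 0.57 in controls 1, 2 and 6, above 0.332, 0.268 and 0.293 in cholate rats 3, 4 and 7. It was -0.691 in control rat 9, -1.103 and -0.744 in cholate rats 8 and 11, and 0.048 in control rat 5. The p over all 10 rats thus does not separate the length trend from the diet.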

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

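The tests by transcript length, cell type, muscle markers, the 6-rat set and the peptidylarginine deiminase region were chosen only after the result was seen, while the splits and the thinning of counts were set before. Of 100 of the 126 splits of the 10 rats into 5 and 5, 1 gave as many as 398 called genes, the diets themselves, and the highest of the others gave 0. Chance is thus argued against for the count but not excluded, since 100 splits resolve no share below 1 in 100. Splits that mix the diets also carry the diet difference into the spread within groups, which can lower their calls.

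The first principal component separates cholate rats 8 and 11 and control rat 9 from the others across the diets. Unequal counting depth is argued against, since after thinning every library to 14337356 counts the component had a correlation of 0.9993 with the original, and 351 genes were called. The rats set apart nonetheless had the lowest totals, 19883925 in control rat 9, 18584910 in cholate rat 8 and 14337356 in cholate rat 11. Thinning removes sampling depth only, so a source that goes with a low total was not tested. A bias by transcript length may underlie it, since loadings had a Spearman correlation of -0.54 with annotated exon length across genes. A different mix of cell types also stays open, as 1 of the 13 cell type lists, goblet cells, had a mean loading beyond all but 0.4% of matched random lists. Apart from the mix of cell types no biological explanation was tested, since the design gives none within a diet.

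The muscle-type genes Des (-3.10), Actn2 (-7.07), Speg (-4.35) and Tnni1 (-3.60) were lower on cholate. Smooth muscle cells as the source of Des are argued against, since in controls Acta2 stood at 0.0132, Actg2 at 0.135 and Tagln at 0.342 CPM against 38.2 for Des. The other measured markers went both ways, with a median log2 change of 0.11 (SD 0.61), Myh11 having -0.86 (10.6 to 5.83 CPM, adjusted p = 0.0138) and Myl9 -0.65, neither called, while Synm, too low to test with all 10 rats, stood at 5.01 to 8.38 CPM in cholate rats 3, 4 and 7 and at most 0.597 in the others. Of further markers too low to test, Synpo2 was lower on cholate (0.493 ± 0.308 to 0.109 ± 0.0773 CPM). Cnn1 (0.117 ± 0.195 to 0.0124 ± 0.0277 CPM) and Tagln (0.342 ± 0.207 to 0.294 ± 0.257 CPM) had lower means within a wide spread. Acta2 (0.0132 ± 0.0184 to 0.157 ± 0.259 CPM) and Actg2 (0.135 ± 0.0869 to 0.142 ± 0.213 CPM) had higher means, also within a wide spread. Pln, Hhip and Cald1, at most 0.0762 CPM in either diet, were too low to give a direction. The fall did not need the rats far along the first component, since among controls 1, 2 and 6 and cholate rats 3, 4 and 7 the median of the 4 genes was -4.46 (SD 1.81). This cannot decide on library quality, since the genes were chosen for their fall in the same rats. On that component these controls (-46.4 to -37.8) also still lay apart from these cholate rats (-31.6 to -26.7). An effect of the diet in the cells sampled may remain as a hypothesis, found and tested on the same data, and other sources such as striated muscle were not tested.

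The peptidylarginine deiminase genes Padi1 (-2.71), Padi2 (-2.80), Padi3 (-2.53) and Padi4 (-1.37), adjacent on chromosome 5 from 159260675 to 159471113, were all called lower, a cluster found by reading through the called genes. A change of the whole region is argued against, since the 15 other measured genes within 500 kb had a median of -0.30 (SD 0.81), a range from -2.34 to 0.46 and none called. For reads of 1 member assigned to the others, the share of Padi2 in the summed CPM was examined. It differed by 17.7 points between libraries (2.27 to 20.0%), between the bounds set for either reading, so that test cannot decide. Reads of Padi4 as the source are argued against, since Padi4 fell less (SE 0.21) than Padi1 (SE 0.28), Padi2 (SE 0.37) and Padi3 (SE 0.32). Padi4 fell from 147.9 ± 30.6 to 57.1 ± 16.2 CPM, where Padi1, Padi2 and Padi3 stood at 9.06, 26.9 and 2.08 CPM in controls. Whether Padi1 and Padi3 took reads of Padi2 cannot be told apart from a joint change. A joint effect of the diet stays open.

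For independent normal values about 13.3 of 266 groups of 5 rats would hold 1 rat far from the others. The groups here share the same 10 rats and CPM values can be skewed, so this figure measures no excess. In 21 of the 266 groups 1 rat lay far from the others. In control rats these were, in CPM, Pla2g2a at 166.4 in rat 6 (others 24.2 to 40.7), Tldc2 at 15.3 in rat 6 (11.3 to 12.2), Slc51a at 23.9 in rat 1 (3.06 to 7.05), Slc19a3 at 1.44 in rat 1 (0.544 to 0.711), Dnase1 at 37.5 in rat 1 (at most 10.2), Oas1a at 22.3 in rat 2 (26.1 to 27.2), and in rat 9 Retnlb at 143.0 (7.50 to 19.9) and Retnla at 245.2 (5.63 to 31.2). In cholate rat 11 they were Ret at 1.75 (1.04 to 1.23), Lbp at 27.2 (at most 15.8), Speg at 1.37 (0.205 to 0.517), Dnase1 at 0.304 (0 to 0.08), Retnla at 0.835 (0 to 0.063) and S100g at 423.8 (59.7 to 146.6). In the other cholate rats they were Akr1b8 at 279.9 (188.0 to 208.5), Slc25a4 at 29.2 (37.3 to 39.4) and Slc19a3 at 0.107 (others 0) in rat 7, Cyp4f1 at 76.8 (6.90 to 26.0) and Nr0b2 at 3.63 (2.18 to 2.51) in rat 8, and F11r at 96.3 (113.8 to 116.0) and Akap2 at 0.308 (0 to 0.08) in rat 4.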

How the results depend on the processing

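The settings with 6 and with 4 rats, matched random lists and a surrogate variable for the lists were chosen after seeing the data. Genes called stayed within 1.5 times of 398 under the other scalings (401, 410 and 474), 2 filters (377 and 357), limma-voom (483), limma-trend (367) and non-robust estimation (412). They numbered 242 (81 higher, 161 lower) with a mean of at least 5 CPM, where fewer genes are tested, 788 (266, 522) by DESeq2, 741 (244, 497) by the edgeR exact test, 1157 (305, 852) by limma-voom with quality weights, 50 (16, 34) by glmTreat and 893 (241, 652) with 1 surrogate variable. At an adjusted p under 0.05 and a fold over 2 they numbered 795 (264, 531), with no fold limit 1704 (802, 902), and at 0.01 with no fold limit 557 (228, 329), looser thresholds by construction. With 1 rat left out the totals ran from 168 to 450 (59 to 152 higher, 109 to 298 lower), with 6 rats 1003 (310, 693), and with controls 5 and 9 and cholate rats 8 and 11 112 (60, 52). Apart from thresholds and the filter, the cause was not tested.

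In the 4-rat set, Abcc4 (-0.38), Abcc3 (-0.016), Nr1i2 (0.064), S1pr2 (0.051) and Nr1i3 (0.093), none of them called, changed sign. No gene checked reversed under a planned setting or without 1 rat, where 106 and 224 calls were lost and 20 and 2 gained (Fabp6, Slc51a, Prdm1, Aqp3, Gnat3 and Prg2). In the 6-rat and 4-rat sets together 70 were lost and 5 gained. Lists called were 16, and 0 with an estimated correlation. Of the 16, 14 were called whichever rat was left out, and 12 in the 6-rat set, where nutrient transport, enteroendocrine, smooth muscle and endothelium were lost. By the adjusted share, which is taken over genes and not over rats, 12 lay beyond matched random lists. NRF2, nutrient transport, enteroendocrine and smooth muscle were lost there, and 2 others gained, glucocorticoid and small intestinal enterocyte. The glucocorticoid list was also gained by fry, in the 6-rat set and without cholate rat 11, neurons and glia by fry, and T and NK cells without control rat 1 or cholate rat 3 or 4. With a surrogate variable 14 stayed called, smooth muscle and endothelium being lost (adjusted p = 0.101 for both), and by fry 15, tuft cells being lost (adjusted p = 0.0745). Cell types that passed were 5, and 0 to 0 with 1 rat left out, where 6 of 10 fits measured 7 smooth muscle markers in place of 6. The smallest possible p is 0.00794 there too, and 1 list at that p cannot pass after adjustment over 13 lists. The coarse test, and not only dependence on single rats, may therefore account for the loss. By the median of the markers, enteric neuron and glia (0.15) and colon segment identity (0.63, adjusted p = 0.0258) reversed. Library properties past the threshold were 0, and 0 to 1 without 1 rat (1 without cholate rat 7). The alternative planned for files with normalized values and no counts was not run, as the file holds counts.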

Other observations

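The vitamin D test here was chosen only after the result was seen, as were the genes named. The calcium channel Trpv6 fell from 172.9 ± 56.2 to 21.5 ± 10.4 CPM (log2 change -3.02, SE 0.35, adjusted p = 0.000957), the calcium binding protein S100g from 1792 ± 735.0 to 173.8 ± 144.1 CPM (-3.37, SE 0.52, adjusted p = 0.00302, but -4.02 without cholate rat 11) and Slc37a2 from 567.9 ± 79.3 to 76.1 ± 35.6 CPM (-2.90, SE 0.31, adjusted p = 0.000659), by edgeR with 5 rats per diet. Slc30a10, also vitamin D responsive, fell by 3.92 (adjusted p = 0.00571), or by 4.71 without cholate rat 4, with the call lost in 6 of the 10 fits that left out 1 rat.

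A candidate explanation is lower output of the vitamin D receptor. Of 11 other vitamin D responsive genes 8 were measured, with a median log2 change of 0.23 (SD 0.64), 3 below 0 and a camera p of 0.965 (0.966 with an estimated correlation). Members went both ways, so this decides nothing, Slc30a10 not being part of the test, and Vdr itself was not called (-0.99, adjusted p = 0.0514).

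Shares of the 13 mitochondrially encoded messages differed in 1 rat of each diet. ND2 took 14.7% of their counts in control rat 6 (95% Wilson interval 14.681 to 14.735) and 17.2% in cholate rat 7 (17.166 to 17.224), against 5.91 to 7.52% in the other 8. COX3 took 11.3% (11.311 to 11.359) and 9.02% (8.999 to 9.043), against 17.2 to 20.6%.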
